A study of Mus musculus with 6 samples.

How the data were processed

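The values used were FPKM (fragments per kilobase of transcript, scaled to the number of mapped fragments), 1 per gene and library, as deposited by the authors. Per the submitters' processing notes, reads were mapped with Bowtie and gene levels were estimated with RSEM on mm10; versions and settings are not given in the sources used here. The labels give an Illumina HiSeq, library preparation from RNA extracted with Trizol and an RNeasy kit, and no batch, sex or per-mouse identity. No reads were analysed here. The table held 18446 genes with NCBI gene identifiers, of which 18326 had a symbol in the reference table and 120 had none; these stayed in the counts but could not be named. No column of per-sample values was left out.

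The genotypes at each time, the 6 h and 48 h responses within each genotype and the difference of these responses were compared on log2(FPKM+1) without rescaling. With 1 library per group, a comparison is a difference of 2 values, so no test was fitted and a gene was counted when it differed by 2-fold or more. Counts used 10347 genes with a mean of 1 FPKM or more over all 6 libraries. No comparison of responses shares a control library between the genotypes, but the difference of responses uses the same 0 h libraries as the comparison at 0 h. Alternatives changed 1 choice at a time: the pseudocount (0.1 or 5 FPKM), the filter (none, or a mean of 5 FPKM or more), the scaling (a common sum, median ratio or upper quartile), the size rule (1.5-fold or 4-fold), and for lists the number of expression bins and the members counted. These choices, the gene lists and the alternatives to each step were fixed before the data were examined, save those described as added.

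The median log2 difference of each list with 5 or more measured members was placed among 10000 random lists of the same size drawn from 10 bins of mean expression, and was called outside below percentile 2.5 or above 97.5. Of 54 lists, 38 had enough members. Random lists were drawn gene by gene, while members of a list may vary together and some genes are on several lists. A percentile therefore describes a list between libraries and is not a test of the label or of time. Genes were named by a fixed rule: Map3k20 and 12 markers of T cell activation and lineage, some of which are not reported here, then the genes with the largest log2 change in each direction among genes with a mean of 5 FPKM or more, 10 each way between the labels, 8 for the WT responses and 5 for the differences of response. Gene models, immunoglobulin and T cell receptor segments were passed over, at most 4 per ranking. For each list outside the range, up to 3 members with the largest change each way could be named. Names outside this rule are said to be chosen after their values were seen.

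GC content and transcript length came from GENCODE M21 transcripts joined on gene identifiers, found for 98.7% of the filtered genes. A 24-base sequence counted as shared when it occurred in transcripts of 50 or more genes; 1548 such sequences were found, and 48.2% of the filtered genes carried at least 1. Centring subtracted the median log2 ratio of 20 bins of GC content and then of 20 bins of length. These features and the lists of liver and chemosensory receptor genes were added after the data were seen.

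In a self-test on simulated values with a 3-fold shift in 200 of 10347 genes, 198 (99.0%) passed the 2-fold rule and 0 unchanged genes did, and 5 of 100 unchanged lists lay outside the range. The simulated genes varied independently, without a GC trend, shared sequences or differences between cultures, and the shifted ones had a mean of 5 FPKM or more. The self-test therefore checks the calculation, and does not give the rate of false calls in these libraries. The value of 1 fragment was estimated from 159 chemosensory receptor genes of 900 to 1000 bases, as their commonest FPKM value within a narrow window. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with random seed 1.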

Results

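Gene expression was measured by RNA sequencing in naive CD4+ T cells, the helper T cells that have not yet met antigen, from wild-type (WT) mice and from mice labelled Zak-deficient. The labels give the genotype as Zak-/- and also speak of a deficiency limited to T cells, so the kind of deletion is not settled. Zak is the MAP kinase kinase kinase encoded by Map3k20, known for activating the p38 and JNK kinases after ribotoxic stress. The cells were sorted by flow cytometry from spleen and lymph nodes and were taken before stimulation (0 h) or after 6 h or 48 h with antibodies against CD3 and CD28, which engage the T cell receptor (TCR) and its costimulatory partner. The design crossed 2 genotypes with 3 times and gave 6 libraries, 1 per group. There were no replicates, so no difference at a single time or between times has a replicate check, and no p-value is given. Deposited FPKM values covered 18446 genes and summed to between 496045 and 546113 per library. Between 1777 and 2793 genes per library were listed at 0, the fewest in the 48 h library labelled Zak-deficient and the most in the 48 h WT library. The total read number per library is not known from these values. Among low values of short genes, the commonest, taken as 1 fragment, was 0.07 FPKM in 5 libraries and 0.06 in the 48 h WT library. It was searched for only within a narrow window, so it does not show that the depths were similar. In the 48 h WT library it rested on 8 genes.

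Map3k20 (chromosome 2, 72285637 to 72442610, mm10) was close to the detection limit in the resting and 6 h libraries. It stood at 0.17 FPKM in WT and 0.10 in the library labelled Zak-deficient at 0 h, and at 0.19 and 0.10 at 6 h. At 48 h it was higher in both, with 1.35 FPKM in WT and 1.61 in the library labelled Zak-deficient. The gene-level value sums all transcripts and cannot show whether an exon was deleted. At 48 h the level therefore did not separate the genotypes as labelled, and at 0 and 6 h the values were too low to do so firmly. For this reason the second genotype is called the library labelled Zak-deficient throughout, and each direction between the genotypes rests on that label.

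Time after stimulation separated the libraries far more than the label did. Across 10347 genes of mean 1 FPKM or more, the log2(FPKM+1) values of the same-time libraries correlated at 0.995 at 0 h, 0.992 at 6 h and 0.983 at 48 h (Pearson's r). Resting and stimulated WT cells correlated at 0.923 at 6 h and 0.796 at 48 h. These correlations run across genes, which are not independent replicates. The median gene differed 1.06-fold between the labels at 0 h, 1.10-fold at 6 h and 1.06-fold at 48 h. The 99th percentile of the difference was 1.52-fold, 1.57-fold and 3.12-fold at these times.

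After 6 h of stimulation, WT cells carried an early activation profile. Cd69, an early activation marker, was 15.4-fold higher (278.2 against 17.1 FPKM), Myc 13.4-fold higher (166.3 against 11.5), and Il2ra, the alpha chain of the IL-2 receptor, 8.98-fold higher (99.7 against 10.2). Il2 itself stood at 12.1 FPKM against 0.07 at rest. By the 2-fold rule, 924 genes were higher and 144 lower; with each library rescaled to a common sum, 871 and 360 were. All folds are on the log2(FPKM+1) scale, which understates the change of low genes.

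The genes with the largest 6 h change in WT had varied functions. Spry1, an inhibitor of ERK signalling, stood at 143.3 FPKM against 0.80 at rest (80.2-fold), and Irf4, a transcription factor of activated lymphocytes, at 208.8 against 2.89 (53.9-fold). Tnfrsf9, the costimulatory receptor 4-1BB, was 50.7-fold higher and Egr2, a zinc-finger factor induced by the TCR, 33.9-fold higher. Akr1c18 (a steroid dehydrogenase), Hivep3, Rgs16 (a regulator of G-protein signalling) and Psat1 (serine synthesis) were between 35.2-fold and 63.3-fold higher. Among the lower genes were Klf3, a Krüppel-like repressor (117.7 to 45.1 FPKM), the sialyltransferase gene St8sia6 (70.9 to 26.9), Rflnb (217.8 to 84.4), the nuclear receptor gene Nr2c2 (39.3 to 14.9), the phosphatase gene Cdc25b (46.2 to 17.7) and the phosphodiesterase gene Pde2a (107.5 to 42.2), all between 2.51-fold and 2.57-fold lower. H2-Q6 (3.19-fold lower) and Tmem254c (20.7 to 0.01 FPKM) also ranked here, but each has near-identical copies, and their values are uncertain.

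The medians of the 38 gene lists with 5 or more measured members were set against 10000 random lists matched on expression. At 6 h in WT, 21 lay outside the central 95%, where lists of independent genes would give 1.9. The cytokine list had the highest median log2 change, 3.06 (percentile 100), with 10 of 13 members at least 2-fold higher. Tnf stood at 127.4 FPKM against 2.95, and the chemokine gene Ccl4 at 19.6 against 0.19. Xcl1, another chemokine gene, was listed at 0 at rest and at 15.6 FPKM at 6 h. Genes linked to ATF4 and amino acid supply followed, with 21 of 23 at least 2-fold higher (median 2.34, percentile 100), among them asparagine synthetase Asns (18.4 against 0.13) and Phgdh, which opens serine synthesis (186.8 against 14.3). Of the Myc-linked ribosome biogenesis genes, 25 of 28 were at least 2-fold higher (median 1.98, percentile 100). The nucleolar genes Nolc1 (99.1 against 13.9) and Gnl3 (109.3 against 15.5) were examples. Of the amino acid transporters 9 of 11 passed 2-fold (median 1.89, percentile 100), with Slc7a5, the large neutral amino acid transporter, at 145.8 against 5.38 FPKM.

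The TCR-induced list itself had 19 of 29 members at least 2-fold higher at 6 h in WT (median 1.70, percentile 100). Further lists with a higher median covered inhibitory receptors and TCR brakes (1.23; Egr3 at 42.0 against 0.45 FPKM), follicular helper genes (1.63; Pou2af1 at 56.5 against 3.58), heat shock genes (1.16; the chaperonin gene Hspd1 at 201.5 against 34.9) and translation factors (1.08; Eif5a at 902.0 against 178.5). The same held for sterol synthesis (1.07; squalene epoxidase Sqle at 22.1 against 1.62), nucleotide and one-carbon genes (1.04; Shmt2 at 237.0 against 19.6) and the unfolded protein response (1.03; the chaperone gene Hspa5 at 329.5 against 64.0). Smaller medians were found for glycolysis (0.88), IL-2 and STAT5 response genes (0.83), MAPK phosphatases (0.78), NF-kB targets (0.58), regulatory T cell genes (0.53) and AP-1 and ATF factors (0.32). Percentiles of these lists ranged from 99.02 to 100. Interferon-stimulated genes had a median of 0.18 (percentile 98.7) with 0 of 28 members at least 2-fold higher. The chemokine receptor and adhesion list had a median of 0.52 (percentile 99.7) with 5 members at least 2-fold higher and 3 lower, but its median was -0.34 among members of mean 5 FPKM or more. Only the naive and quiescence list had a lower median at 6 h (-0.83, percentile 0), with 23 of 24 members below 0. The quiescence factor gene Tob1 stood at 27.3 FPKM against 61.9, and Rasgrp2 at 45.2 against 104.5.

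At 48 h, WT cells had the profile of cycling cells. Mki67, the proliferation marker Ki-67, stood at 92.6 FPKM against 0.51 at rest (62.0-fold higher), Top2a, a topoisomerase of dividing cells, at 156.3 against 1.28 (69.0-fold), and Ccna2, which encodes cyclin A2, at 82.7 against 0.43 (58.5-fold). Il7r, the IL-7 receptor that keeps naive T cells alive, was 102.9-fold lower, at 4.11 against 524.6 FPKM. In all, 1840 genes were at least 2-fold higher and 1273 at least 2-fold lower.

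Other genes that ranked highest at 48 h in WT were Nrn1 (92.6-fold higher, 202.7 against 1.20 FPKM), Hivep3 (65.2-fold), the glycolytic enzyme gene Tpi1 (60.1-fold, 590.1 against 8.83), Ifitm2 (56.8-fold) and Spry1 (56.8-fold). The lowest were led, after Il7r, by Rflnb (40.1-fold lower), Ly6c1 (33.1-fold), the sorting gene Vps37b (28.9-fold, 18.6 against 563.6 FPKM), Pde2a (27.6-fold) and S1pr1, the receptor that lets T cells leave lymph nodes (25.6-fold, 13.2 against 363.7). Tubb2a and Klrd1 were 24.2-fold and 21.6-fold lower. Cd69 (83.8 FPKM), Myc (98.8) and Il2ra (89.6) were still above their resting level, by 4.67-fold, 7.97-fold and 8.08-fold. Il2 stood at 13.6 FPKM.

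Of the G2 and M phase genes 31 of 32 were at least 2-fold higher at 48 h in WT (median log2 change 4.28), and of the S phase genes 32 of 33 (3.13), with the replication factor gene Uhrf1 at 110.3 against 0.99 FPKM. Glycolysis genes followed with 18 of 21 (2.56; lactate exporter Slc16a3 at 86.4 against 3.08), nucleotide and one-carbon genes with 21 of 25 (2.45; Rrm2 at 122.7 against 1.84), and Myc-linked ribosome biogenesis genes with 23 of 28 (1.82). The G1 list had 9 of 13 members at least 2-fold higher (2.20), among them cyclin D2 (Ccnd2, 162.1 against 19.4), while the cell cycle inhibitor Cdkn1b was lower (31.2 against 157.3). Cytokine genes kept a high median (2.84, 10 of 13 members at least 2-fold higher), as did the ATF4-linked (1.81), sterol synthesis (1.54; Cyp51 at 50.2 against 2.77), heat shock (1.44), amino acid transporter (1.37), IL-2 and STAT5 response (1.36), TCR-induced (1.24) and translation factor (1.21) lists. Medians between 0.79 and 0.90 were found for the unfolded protein response, regulatory T cell genes, inhibitory receptors, p53 targets, apoptosis regulators and memory and effector markers. The last group included the galectin gene Lgals1 (123.7 against 18.9). All of these lists lay at or above the 98.8th percentile of random lists.

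Lower medians at 48 h in WT were found in 4 lists. The naive and quiescence list had 18 of 24 members at least 2-fold lower (-2.15, percentile 0), with the PI3K inhibitor gene Pik3ip1 at 10.6 against 176.5 FPKM besides Il7r and S1pr1. TGF-beta response genes had 6 of 11 (-1.46, percentile 0), with Smad7 at 3.59 against 55.2 and the receptor gene Tgfbr2 at 19.7 against 116.8. The MHC class I list had 5 of 16 members at least 2-fold lower (-0.47, percentile 1.89), with H2-K1 at 599.7 against 2104; without genes that carry a shared sequence the median was 0.09 and inside the random range. Interferon-stimulated genes went both ways: 9 of 28 were at least 2-fold lower, such as Irf7 (0.98 against 17.9), and 5 were higher, such as the guanylate-binding protein gene Gbp2 (107.9 against 12.2). Their median was -0.55 (percentile 0.27), and 0.15 among members of mean 5 FPKM or more.

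**Figure D1:**
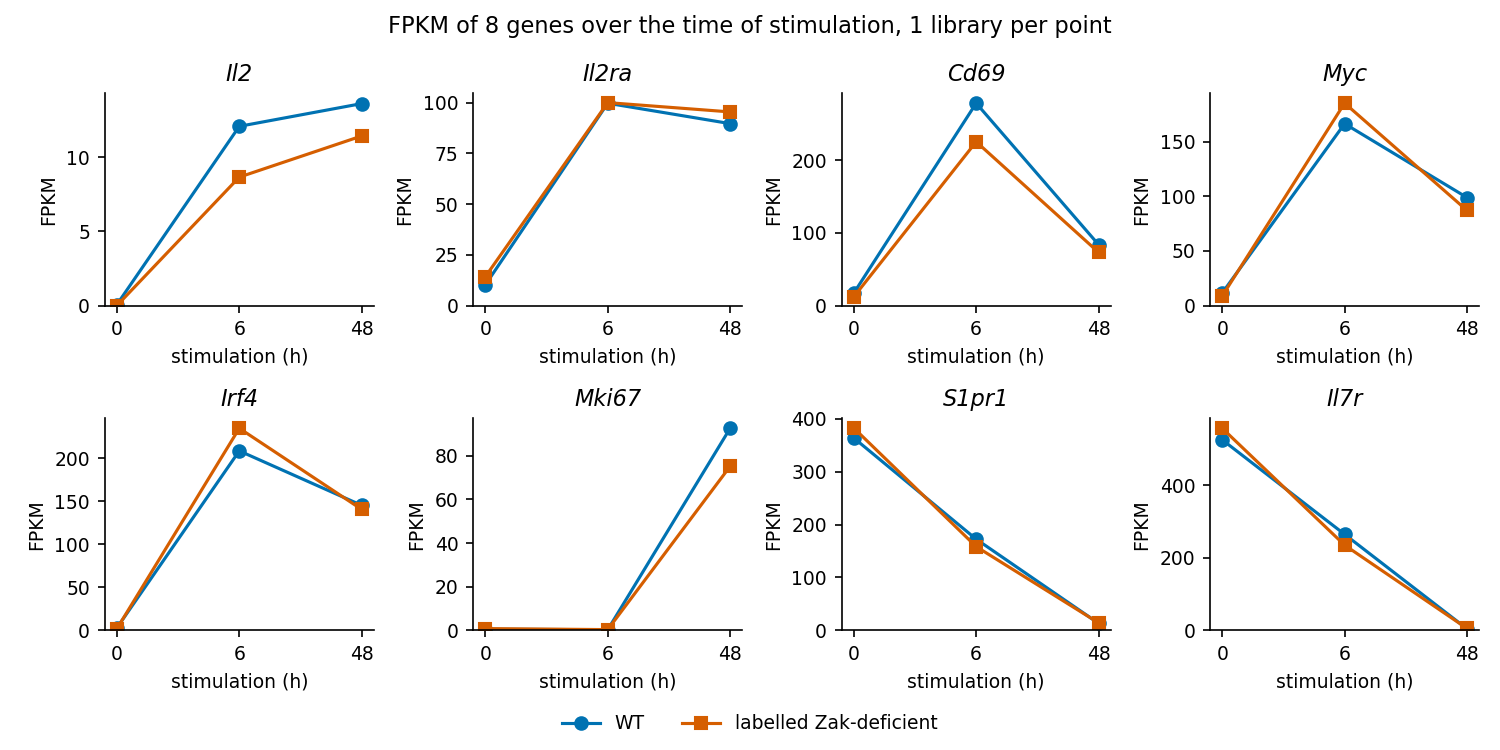
FPKM (vertical axes, linear) of 8 genes in the 6 libraries against the hours of stimulation (horizontal axes, 0, 6 and 48 h, evenly spaced), with circles for WT and squares for the libraries labelled Zak-deficient, 1 library per point. Cd69 was highest at 6 h (278.2 FPKM in WT and 225.2 in the library labelled Zak-deficient), Mki67 at 48 h (92.6 and 75.2), and Il7r at 0 h (524.6 and 556.3).

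The libraries labelled Zak-deficient carried the same time course. Against their own 0 h library, 939 genes were at least 2-fold higher and 157 lower at 6 h, and 1909 were higher and 1246 lower at 48 h. With upper quartile scaling 848 were higher and 306 lower at 6 h. Of the WT genes, 791 of 924 higher at 6 h (85.6%) and 1699 of 1840 higher at 48 h (92.3%) passed the rule under the other label too, where independent lists of these sizes would share 83.8 and 339.5. For lower genes the shared numbers were 53 of 144 at 6 h (2.19 if independent) and 1052 of 1273 at 48 h (153.3). Log2 responses correlated across genes at 0.93 at 6 h and 0.96 at 48 h. In opposite directions the rule was passed by 2 genes at 6 h, the histone gene H4c4 (uncertain) and a gene model, and by 7 at 48 h, which include Il11, Smco1 and Gje1; H4c4 was chosen after its values were seen. Under the label Zak-deficient, Spry1 stood at 164.1 FPKM at 6 h against 0.79 at rest, Irf4 at 235.1 against 1.92 and Top2a at 135.1 at 48 h against 1.13. Most medians were near those of WT, such as 1.82 for TCR-induced, 2.91 for cytokine and 2.04 for ribosome biogenesis genes at 6 h, and 4.24 for G2 and M phase, 3.05 for S phase and -2.04 for naive and quiescence genes at 48 h. Others were not: at 6 h interferon-stimulated genes had a median of -0.12 and lay inside the random range, against 0.18 in WT, and MAPK phosphatases had 1.28 against 0.78. In number, 21 lists lay outside the range at 6 h and 24 at 48 h, as in WT, though not all were the same ones.

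At rest, genes induced by the TCR were slightly lower in the library labelled Zak-deficient than in WT. The TCR-induced list had a median log2 ratio of -0.16 with 21 of 29 members below 0 (percentile 0), among them Fos, a component of AP-1 (3.26 against 5.70 FPKM), Egr2 (0.74 against 1.52) and Cd69 (12.01 against 17.13). In the same direction went MAPK phosphatases and feedback genes (-0.12, 15 of 18 below 0, percentile 0.07; Gadd45b at 23.02 against 34.12) and NF-kB targets (-0.09, 18 of 23, percentile 0.14; the adhesion molecule gene Icam1 at 9.02 against 12.1). Regulatory T cell genes had a higher median (0.14, 9 of 12 above 0, percentile 99.98), with Il2ra at 14.2 against 10.2, the inhibitory receptor gene Ctla4 at 67.9 against 52.0 and Foxp3, their lineage factor, at 16.0 against 14.1. Il2ra and Ctla4 are on the TCR-induced list too, where they went against its median. With a pseudocount of 5 FPKM the MAPK phosphatase median was -0.05 and inside the range. No member of these lists differed 2-fold. Markers of B cells were also apart, with a sum of 10.98 FPKM against 5.94, among them Cd79a at 3.79 against 2.04, chosen after its values were seen.

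By the 2-fold rule 28 genes differed at 0 h, 23 higher and 5 lower in the library labelled Zak-deficient, 2 of the lower ones being gene models. Several of the named ones belong to sets of near-identical copies: Eif3j2 was higher (8.03-fold, 15.9 against 1.11 FPKM) while Eif3j1 was lower (2.10-fold), and Tmem254b was higher (4.08-fold) while Tmem254c was lower (11.02-fold). The values of such pairs are uncertain, as are those of Slc28a2b (2.36-fold lower, 133.8 against 316.9), H2-Q6 (1.70-fold lower), Xlr3b (2.21-fold higher), Rpl34-ps1 (1.72-fold lower) and the histone genes H4c9, H2ac24 and H2ac18. The other higher genes were Zfp457 (2.86-fold), Cerkl (2.21-fold, 18.7 against 7.91), Inafm2 (2.16-fold), the cytokine gene Il11 (2.08-fold, 24.6 against 11.3) and Nkain3 (2.07-fold). Of these, Il11 and Nkain3 carry a sequence shared by many transcripts, so their values are uncertain too. They belong to the genes at least 2-fold higher at 48 h, described below, whose median log2 ratio was 0.33 at 0 h and -0.13 at 6 h. Lower genes under 2-fold were Stt3b, a subunit of the oligosaccharyltransferase (1.71-fold, 43.5 against 75.2), the fatty acid binding protein gene Fabp5 (1.69-fold, uncertain for its shared sequence), Sco2 (1.61-fold), which serves cytochrome c oxidase assembly, and Ly6c1 (1.60-fold, uncertain beside its close copy Ly6c2).

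Of the 38 lists, 10 lay outside the random range at 0 h, where lists of independent genes would give 1.9. List members may vary together, so a difference between 2 cultures could place as many outside. Besides those above, IL-2 and STAT5 response genes had a higher median (0.07, percentile 99.6, 11 of 19 above 0), which was 0.01 and inside the range among members of mean 5 FPKM or more. Lower medians were found for cytokine genes (-0.10, percentile 2.09; Tnf at 1.76 against 2.95 FPKM), housekeeping genes (-0.07, 1.56), glycolysis genes (-0.07, 1.47), the unfolded protein response (-0.06, 1.38) and MHC class I genes (-0.06, 2.47). The cytokine median was 0 when all members above 0 were counted, and the glycolysis (-0.05) and MHC class I (-0.03) medians were inside the range once ratios were centred on GC content and transcript length, a check added after the data were seen. Without genes that carry a sequence shared by many transcripts, all of these lists but those of the TCR-induced, regulatory T cell, MAPK phosphatase and NF-kB genes were inside it, housekeeping (-0.08) and unfolded protein response genes (-0.07) included. The other medians were 0.07 for IL-2 and STAT5 response genes and -0.08 each for glycolysis, MHC class I and cytokine genes. These calls thus ended with medians close to those before. Centring also placed interferon-stimulated genes outside the range, with a lower median (-0.08, percentile 1.99).

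After 6 h, the order of the TCR-induced genes between the labels was the opposite of that at rest. The list had a median log2 ratio of 0.17 with 22 of 29 members above 0 (percentile 100). Nr4a1, an orphan receptor induced by TCR signals, stood at 1010.0 FPKM in the library labelled Zak-deficient against 734.0 in WT, the NF-kB subunit gene Rel at 27.8 against 20.8, and Nfatc1 at 137.7 against 104.2. Members lower under that label included Cd69 (225.2 against 278.2), the CD40 ligand gene Cd40lg (125.0 against 148.3) and Cd44 (2.76 against 3.71). Inhibitory receptors and TCR brakes also had a higher median (0.16, 14 of 21 above 0, percentile 99.97), led by the inhibitory receptor gene Lag3 (9.04 against 3.48, 2.24-fold), the ubiquitin ligase gene Cbl (18.6 against 13.8) and Dgkz (151.7 against 114.6). Interferon-stimulated genes were lower, with 24 of 28 members below 0 and a median of -0.26 (percentile 0), such as Gbp2 (14.4 against 24.1), Ifit3 (2.26 against 3.96) and the immunity-related GTPase gene Irgm1 (16.1 against 23.2). Il2 stood at 8.65 FPKM against 12.1 in WT, 1.35-fold lower.

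Between the 6 h libraries 25 genes differed 2-fold, 12 higher and 13 lower under the label Zak-deficient. Higher, besides Eif3j2 (14.6-fold, uncertain) and Lag3, were the potassium channel gene Kcna3 (2.04-fold, 16.2 against 7.44 FPKM), Scand1 (1.85-fold), Inafm2 (1.81-fold), Trim56 (1.79-fold), the histone demethylase gene Kdm6b (1.78-fold, 126.1 against 70.3), Eps8l1 (1.74-fold) and Dusp5, a phosphatase for ERK (1.72-fold, 96.9 against 55.9). Lower were Zfp972 (2.06-fold, 16.7 against 35.5), Pglyrp1 (1.81-fold), Trappc2 (1.78-fold), the mitophagy gene Bnip3 (1.77-fold) and Phf11b (1.77-fold). Lag3, Trim56, Kdm6b, Dusp5, Pglyrp1 and Trappc2 carry a sequence shared by many transcripts, as do 48.2% of the filtered genes. Their values are uncertain for that reason. The values of Rpl37rt (2.17-fold lower), Slc28a2b (2.15-fold lower), Eif3j1 (2.08-fold lower), Tgtp2 (1.90-fold lower), the dynein light chain gene Dynlt1c (1.81-fold lower) and H2-Q6 (1.94-fold higher) are uncertain because of near-identical copies.

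The ratios between the 6 h libraries followed the GC content of the transcripts. Spearman's rho between log2 ratio and GC content was 0.52 across 8115 genes, against -0.13 at 0 h and 0.13 at 48 h; genes are not independent replicates. The median ratio ran from -0.17 in the 10% of genes with the lowest GC content (median 39.6%) to 0.19 in the 10% with the highest (59.0%). After centring on GC content and length, the TCR-induced list still had a median of 0.14 and the interferon-stimulated list -0.26, both outside the random range. So did the inhibitory receptor and memory and effector lists; the latter had a median of -0.22 before centring (percentile 0.11), with Lgals1 at 11.5 against 18.7 FPKM and the chemokine receptor gene Cxcr6 at 0.67 against 3.50. Sterol synthesis genes (0.13, percentile 99.6, 18 of 23 above 0), such as Srebf2 (91.7 against 61.8), also stayed outside after centring, though not once genes with a sequence shared by many transcripts were left out (0.11). Centring ended the call of 5 lists: TCR signalling components (0.07 before, 0.003 after), TGF-beta response (0.18 and 0.04), cytosolic ribosomal protein (-0.14 and -0.06), translation factor (-0.16 and -0.04) and histone genes (-0.24 and -0.10). It also placed 2 lists outside the range, cytokine genes with a higher median (0.08, percentile 98.4) and S phase genes with a lower one (-0.10, percentile 0.22).

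**Figure D2:**
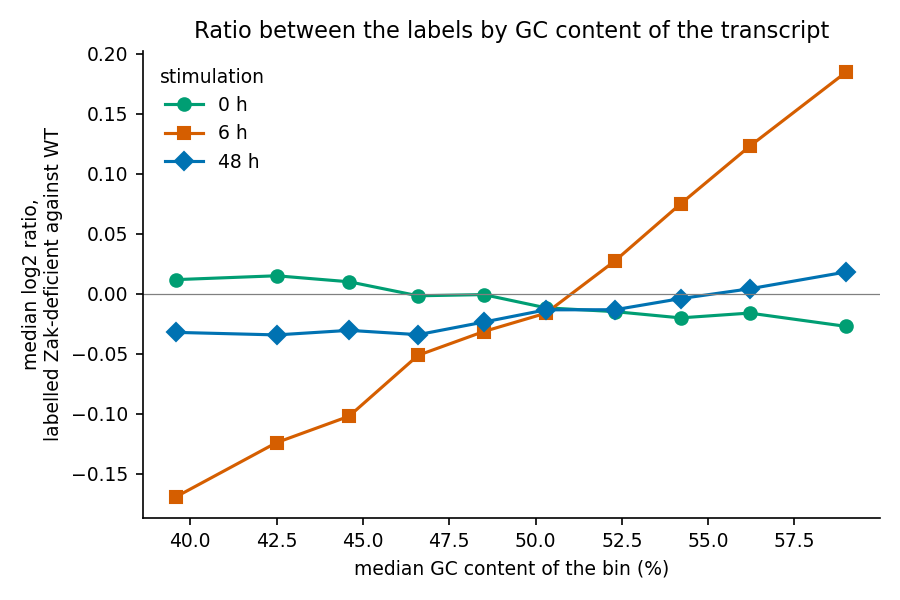
Median log2 ratio of the library labelled Zak-deficient against WT (vertical axis) in 10 groups of genes ordered by the GC content of their transcripts (horizontal axis, median GC content of the group in percent), with 1 line per time. At 6 h the median ran from -0.17 at 39.6% to 0.19 at 59.0%, while at 0 h and 48 h all groups lay between -0.03 and 0.02.

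At 48 h, genes of mitosis and ribosome biogenesis were slightly lower in the library labelled Zak-deficient, while S phase genes (-0.01, percentile 64.3) and G1 genes (-0.03, percentile 35.4) lay inside the random range. The G2 and M phase list had a median log2 ratio of -0.12 with 30 of 32 members below 0 (percentile 0), among them Mki67 (75.2 against 92.6 FPKM), cyclin B1 (Ccnb1, 42.1 against 51.6) and the kinesin gene Cenpe (9.49 against 11.8). Myc-linked ribosome biogenesis genes had the same median with 25 of 28 below 0 (percentile 0; Nolc1 at 75.9 against 91.3), and translation factors -0.10 with 19 of 21 (percentile 0; Eif5a at 912.4 against 1027). Cytokine genes had a median of -0.23 with 9 of 13 below 0 (percentile 0), such as lymphotoxin alpha (Lta, 19.7 against 30.7) and Ccl4 (13.1 against 18.1), while Xcl1 was higher (8.75 against 6.21). Naive and quiescence genes had a higher median (0.09, 16 of 24 above 0, percentile 100), led by Klf2 (45.5 against 31.3) and Cxcr4 (14.7 against 9.53). Cytosolic ribosomal protein genes did too (0.06, 28 of 35, percentile 99.97), with Rps19 at 2356 against 2091.

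Lower medians were also found at 48 h for the unfolded protein response (-0.10, 14 of 19 below 0, percentile 0.11; Hspa5 at 204.6 against 235.9 FPKM) and for Th1 genes (-0.16, 8 of 10, percentile 0.15). Among the latter, granzyme B (Gzmb) stood at 6.42 against 9.36. The Th1 call ended among members of mean 5 FPKM or more (-0.04) and with a pseudocount of 5 (-0.07), and the cytokine median was 0 when all members above 0 were counted. In all, 8 of 38 lists lay outside the random range, and no member of these lists differed 2-fold. Centring on GC content and length also placed regulatory T cell genes (0.07, percentile 97.66) and sterol synthesis genes (0.05, percentile 97.55) outside it, with higher medians. The lineage factor genes were close: Foxp3 stood at 7.65 FPKM against 5.90, Gata3 at 7.19 against 6.26, Bcl6 at 5.88 against 5.60 and Tbx21 at 0.36 against 0.52. Ifng was at 0.05 against 0.23, values that rest on a few fragments.

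Single genes stood apart at 48 h in larger number than at the earlier times, 186 higher and 45 lower in the library labelled Zak-deficient. The lower ones were mostly genes of hepatocytes. Mup2, a major urinary protein gene, was 28.4-fold lower (0.16 against 32.0 FPKM), and Alb, which encodes serum albumin, was listed at 0, while the 4 libraries of the earlier times held between 6.29 and 9.50. The apolipoprotein genes Apoc1 and Apoc3, Mup11, Mup19 and the acute-phase gene Saa2 were also listed at 0, against 13.38, 10.46, 13.2, 12.91 and 8.72 in WT. Apoa2 (1.15 against 15.9) and Mup7 (1.07 against 11.8) were lower too. The Mup genes are near-identical copies, so their single values are uncertain. Of the 45 genes, 39 were on lists of liver genes written after the data were seen. The 41 liver genes listed from these values summed to between 135.2 and 263.5 FPKM in the other 5 libraries, the 2 earlier ones labelled Zak-deficient included, and to 4.15 in this library. With the liver genes left out, 6 lower genes remained.

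The higher genes at 48 h were headed by Il11 (29.1-fold, 92.7 against 2.22 FPKM), Smco1 (16.2-fold, 102.2 against 5.39), Zfp457 (11.5-fold, 45.6 against 3.05) and Nkain3 (9.15-fold, 35.8 against 3.02). After them came the gap junction gene Gje1 (7.63-fold), Veph1 (6.03-fold), and the rhodopsin kinase gene Grk1 (5.57-fold). Usp17la (5.13-fold, a member of a family of copies), Eif3j2 (8.40-fold) and Tmem254c (7.94-fold, with Tmem254b 8.98-fold lower) are uncertain. Of the 178 higher genes with a transcript to search, 145 (81.5%) carried a 24-base sequence found in the transcripts of 50 or more genes, against 39.9% to 53.9% in random sets matched on expression. Those sets were not matched on the length or number of a gene's transcripts, which also affect whether such a sequence is found. Zfp457 carried none. At 0 h and 6 h the share was 43.5% and 42.9%, but only 23 and 12 genes were higher at these times, too few for a firm comparison. Without genes of this kind, the 48 h count was 81, 41 higher and 40 lower, in place of 231. Markers of other blood cells were apart at 48 h as well. B cell markers, higher under that label at 0 h too, summed to 17.3 FPKM under the label Zak-deficient against 10.01 in WT, and neutrophil markers at 17.0 against 3.39, where the chemokine receptor gene Cxcr2, which carries such a shared sequence, made up 15.91 and 3.05.

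**Figure D3:**
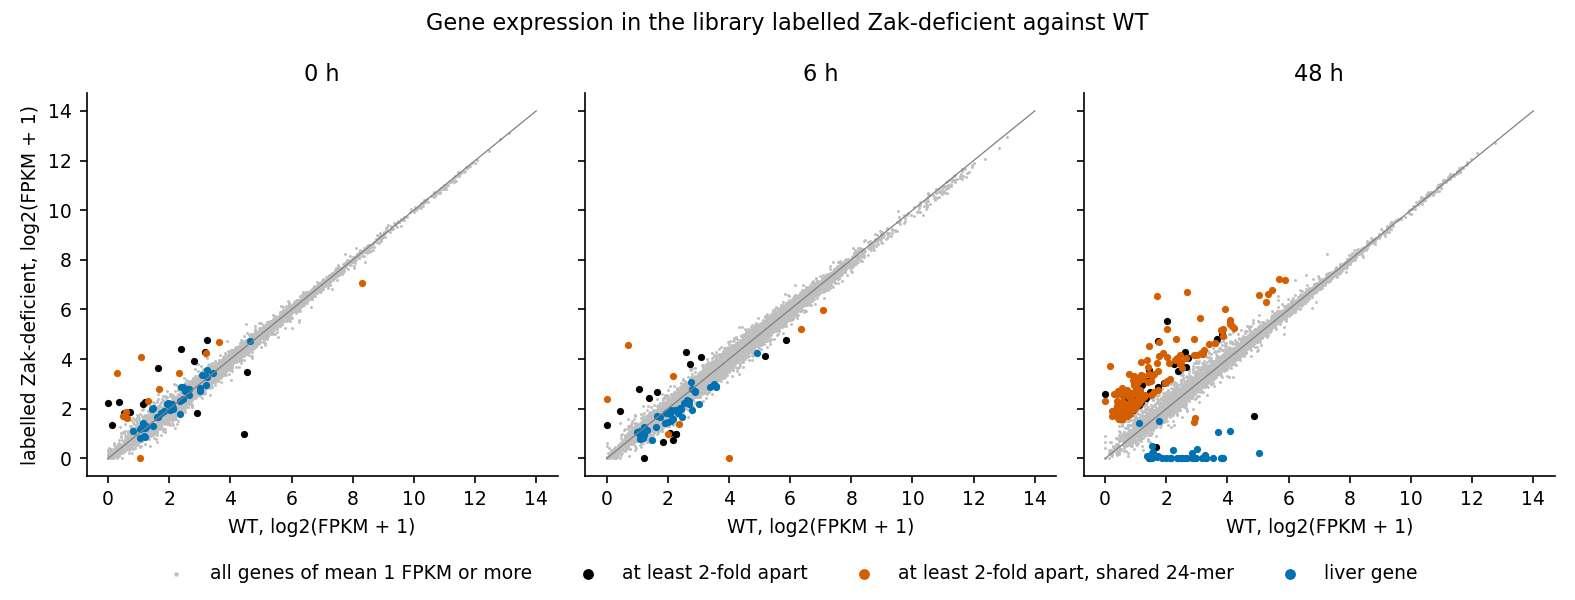
Expression in the library labelled Zak-deficient (vertical axes) against WT (horizontal axes) at 0, 6 and 48 h, both as log2(FPKM+1), with 1 point per gene and a line of equal expression. Genes at least 2-fold apart are black, or orange where they carry a sequence shared by many transcripts, and liver genes are blue; at 48 h the 186 higher genes lie above the line and most liver genes lie at or near 0 on the vertical axis.

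The 6 h response differed between the labels by 2-fold or more for 60 genes, 18 with a larger and 42 with a smaller log2 change under the label Zak-deficient, and for 106 genes with each library rescaled to a common sum. This difference uses the 0 h libraries as well, so it shares its values with both comparisons between the labels above. Lag3 (1.17 on the log2 scale), Kcna3 (1.17), AU020206 (1.14), Tmem254c (3.45, uncertain) and H2-Q6 (1.72, uncertain) had the largest positive differences. Zfp457 (-1.83), Cerkl (-1.34), Nkain3 (-1.21), Tmem254b (-2.67, uncertain) and the pseudogene Gapdh-ps15 (-1.58, uncertain) had the largest negative ones. The TCR-induced list had a median difference of 0.31 with 20 of 29 members above 0 (percentile 100), and MAPK phosphatases 0.29 with 16 of 18 (percentile 100). Dusp5 (0.85) and Dusp4 (0.62) had the largest differences there. Lag3, Nkain3 and Dusp5 carry a sequence shared by many transcripts, so their differences are uncertain. AP-1 and ATF factors (0.16), sterol synthesis (0.19), inhibitory receptors (0.13) and TCR signalling (0.07) were also outside the range, above percentile 98, the last not without genes that carry a shared sequence (0.12). Th2 genes were too (0.22, percentile 98.6, 7 of 7 above 0; Nfil3 0.47), but inside it with all members above 0 (0.03) or a pseudocount of 0.1 FPKM (0.12). The glycolysis (0.10) and TGF-beta (0.16) medians were outside too, but inside the range after centring on GC content and length (0.04 and 0.08), and the TGF-beta median was 0.001 without genes that carry a shared sequence. Interferon-stimulated genes had a median of -0.21 with 24 of 28 below 0 (percentile 0.02). G2 and M phase genes, nearly silent at these times, had -0.12 (percentile 1.06), and -0.02 after centring.

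At 48 h the response differed by 2-fold or more for 184 genes, 129 with a larger and 55 with a smaller log2 change under the label Zak-deficient. The split turned without genes that carry a shared sequence (29 larger, 49 smaller) and under a 4-fold rule (11 and 33). With the liver genes left out, it was 129 and 16. Of the 129, 123 were also 2-fold higher between the 48 h libraries, and of the 55, 42 were 2-fold lower. Tmem254c (6.45, uncertain), Il11 (3.80), Smco1 (3.10), Gje1 (2.19) and Nkain3 (2.14) led the positive side, and Tmem254b (-5.20, uncertain), Mup2 (-4.94), Alb (-3.85), Mup11 (-3.81) and Apoc1 (-3.68) the negative side. Lists with a lower median difference were IL-2 and STAT5 response genes (-0.21, 13 of 19 below 0, percentile 0; Lta -0.84), Th1 genes (-0.14), cytokine genes (-0.14), G2 and M phase genes (-0.12, 27 of 32), ribosome biogenesis genes (-0.11, 23 of 28) and translation factors (-0.09). Higher medians were found for MAPK phosphatases (0.19), sterol synthesis (0.11), naive and quiescence (0.11, 20 of 24 above 0) and ribosomal protein genes (0.10, 28 of 35). Before any centring, the IL-2 and STAT5, MAPK phosphatase and sterol lists lay inside the random range between the 48 h libraries. The IL-2 and STAT5 and MAPK phosphatase lists lay outside it at 0 h, in the opposite direction. Their differences therefore rest in part on the 0 h libraries. Without genes that carry a shared sequence, the G2 and M phase (-0.10) and ribosome biogenesis (-0.09) medians were inside the range, and the sterol median was with a mean of 5 FPKM or more (0.08) or a pseudocount of 5 FPKM (0.07). The Th1 median (-0.16) was inside it too with a mean of 5 FPKM or more. The cytokine median was 0.11 among members of mean 5 FPKM or more, and the translation factor median was -0.06 and inside the range after centring on GC content and length.

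**Figure D4:**
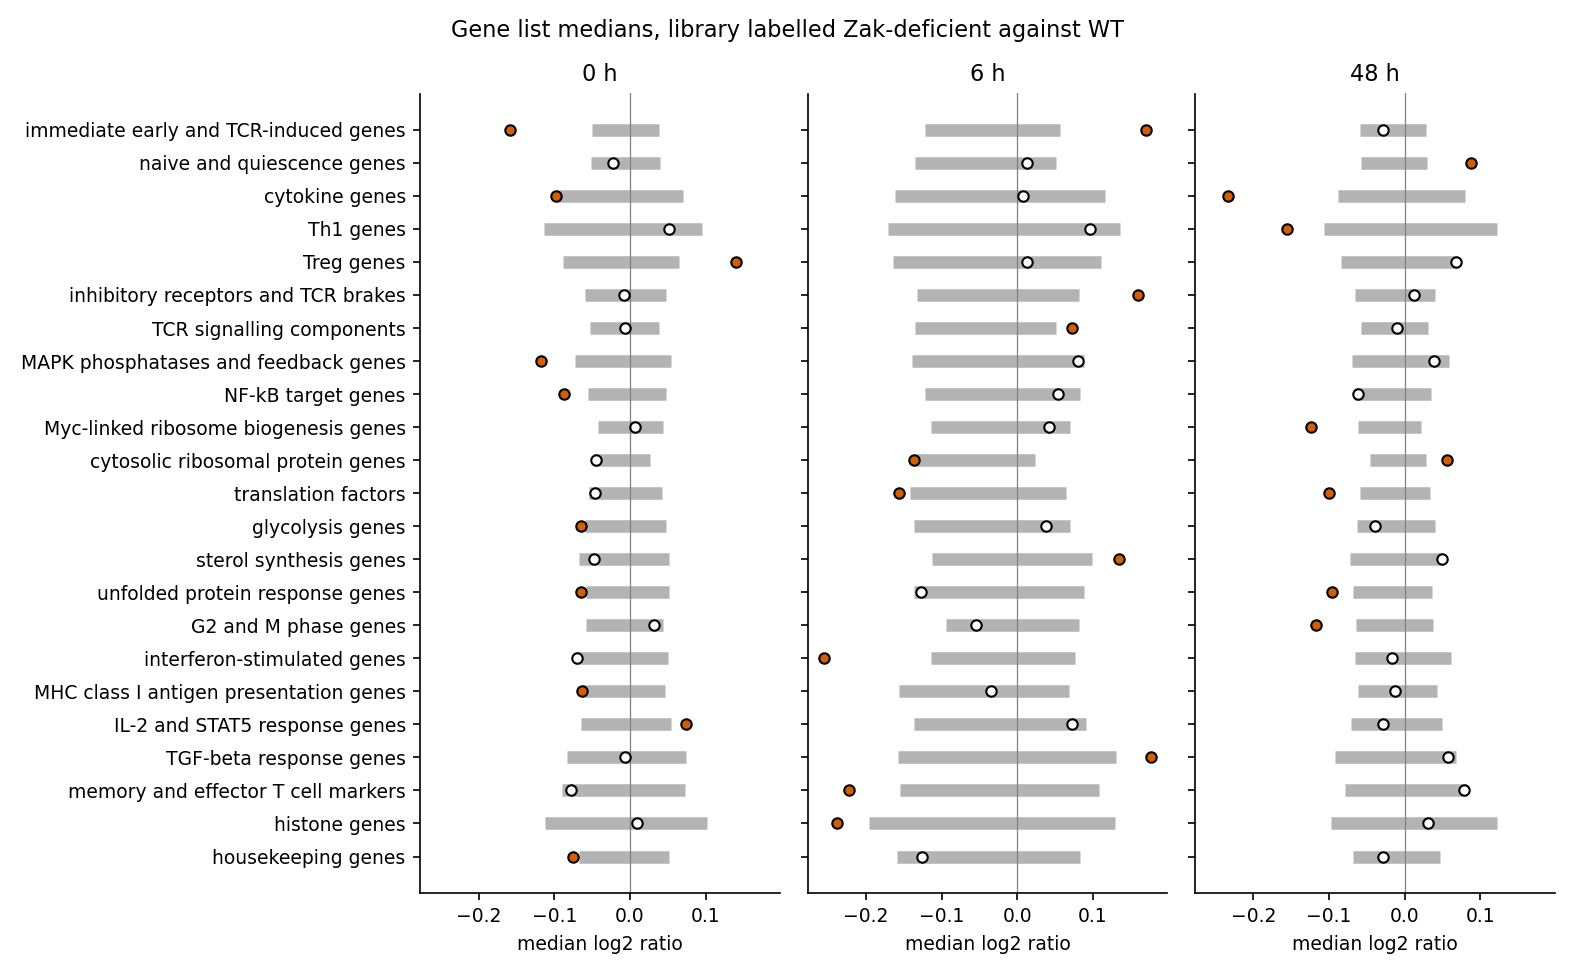
Median log2 ratio of 23 gene lists, library labelled Zak-deficient against WT (horizontal axes), at 0, 6 and 48 h, with 1 point per list, filled where the median lay outside the central 95% of 10000 random lists matched on expression (grey bars). The TCR-induced list lay at -0.16 at 0 h and 0.17 at 6 h, and the interferon-stimulated list at -0.26 at 6 h.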

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

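The tests on liver RNA by summed level and on GC content and transcript length were chosen before their results were seen, and those on liver RNA gene by gene, on the label at every time, on shared sequence and on genomic DNA after. The results below stand out because the same contrast went in opposite directions in different groups; with 1 library per group, none of these differences was tested.

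Several genes responded in opposite directions at 48 h under the labels. The log2 response of Il11 was -1.93 in WT and 1.87 under the label Zak-deficient, a difference of 3.80 that was not tested. For Smco1 it was -1.83 and 1.26 (difference 3.09), and for Gje1 -1.09 and 1.10 (difference 2.19). Between the copies Tmem254b and Tmem254c the values crossed over. The response of Tmem254b was 2.47 in WT and -2.72 under the label Zak-deficient (difference -5.20), and that of Tmem254c -2.70 and 3.75 (difference 6.45). The same 2 values, -5.20 and 6.45, are the differences between their label ratios at 48 h and at 0 h. The summed FPKM of both copies stood at 30.53 in WT and 27.76 under the label Zak-deficient at 48 h. It was 24.97 and 21.45 at 0 h, and farther apart at 6 h, at 19.13 and 11.89.

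The TCR-induced list had a label ratio that was negative at 0 h and positive at 6 h, with a median change of 0.311 over its members. Cytosolic ribosomal protein genes had a negative ratio at 6 h and a positive one at 48 h, with a median change of 0.214. Neither difference was tested. The ribosomal protein ratio at 6 h was inside the random range after centring on GC content and length, at -0.06.

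The genes that were lower at 48 h under the label Zak-deficient may reflect liver RNA carried into the other 5 libraries. An effect of the label at every time is argued against, since the higher of their median log2 ratios at 0 h and 6 h was 0.102. The summed level of 72 held-out liver genes was 75.2% of the lowest other library, past the 67% set beforehand as speaking against liver RNA. That bound was a poor one, because a sum leans on its highest genes: Fah (1.84), Lcat (1.66) and Apof (1.26), chosen after their values were seen, gave much of the 10.51 FPKM in this library, where 34 of the 72 were above 0 against 60 to 66 in the others. Gene by gene, 33 of the 72 were lowest in this library, where independent genes would give 12, with at most 18 in the central 95%. Genes of 1 library are not independent replicates, so that range is too narrow for genes that vary together. The summed test and the count by gene point apart, and the liver source stays open. The sort for CD4+ cells should have removed hepatocytes, and a biological effect of the label at 48 h alone is untested.

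The genes that were higher at 48 h, Il11, Smco1 and Gje1 among them, may reflect reads from a sequence shared by many transcripts. Of those searched, 81.5% carried such a sequence, against 47.2% in the median random set, which was matched on expression but not on transcript length or number. A larger share of genomic DNA in this library is a candidate source of such reads. Their excess over the lowest library, as a percent of that in this library, was 22.3% in the 6 h WT library against 78.5% for chemosensory receptor genes; in the 3 other libraries where it could differ the gap was under 20 points, at most 14.93% against 31.9% in the 6 h library labelled Zak-deficient, so genomic DNA and other sources cannot be told apart. The genes were selected on the 48 h pair, so their values do not say which of its libraries stands apart; an effect of Zak deficiency at 48 h is untested, as is a separate preparation of either library, for which the labels give no batch.

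The 6 h ratios of the TCR-induced and interferon-stimulated lists were weighed against the GC trend between these libraries. After centring on GC content and length, the TCR-induced median was 0.139 (0.17 before) and the interferon-stimulated median -0.265 (-0.255 before), both outside the range of random lists. The trend therefore does not account for either list as a whole. An effect of the label, a difference in the timing of stimulation and a difference between cultures stay open and untested.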

How the results depend on the processing

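The settings that centred on GC content and length, left out liver genes or genes with a shared sequence, or filtered over 5 libraries were added after the data were seen; the others were planned. Where a count moved beyond 1.5 times, the cause was not tested unless the setting itself changes the threshold or removes genes.

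A 1.5-fold rule gave 116, 171 and 437 genes between the labels at 0, 6 and 48 h, 3098 and 5472 for the WT responses at 6 and 48 h, 3098 and 5491 under the label Zak-deficient, and 349 and 491 for the differences of response. A 4-fold rule gave 6, 3 and 66, then 237 and 831, 248 and 868, and 8 and 44. With a pseudocount of 5 FPKM the counts were 7, 5 and 76, then 666 and 1970, 695 and 1955, and 9 and 53. With a pseudocount of 0.1 FPKM, 97 genes differed at 0 h and 86 at 6 h, and the differences of response counted 204 and 354. A mean of 5 FPKM or more left 13, 9 and 73 between the labels and 27 and 58 for the differences of response. Without genes that carry a shared sequence, 16 genes differed at 0 h and 81 at 48 h, the WT responses counted 628 and 1728, those under the label Zak-deficient 645 and 1737, and the differences of response 39 and 78. Rescaling each library to a common sum gave 106 for the difference of the 6 h response. The 9 counts stayed within 1.5 times with median ratio or upper quartile scaling, centring on GC content and length, no filter and without liver genes. Without liver genes, though, the lower genes at 48 h went from 45 to 6, and genes with a smaller 48 h response from 55 to 16.

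The split into higher and lower genes depended on the scaling and on the size rule. At 6 h in WT 86.5% were higher, and 70.8% after rescaling to a common sum or 71.3% after upper quartile scaling. Under the label Zak-deficient 85.7% were, and 73.5% after upper quartile scaling. With the 1.5-fold and 4-fold rules the higher share at 6 h was 56.8% and 99.6% in WT, and 55.6% and 100% under the label Zak-deficient. Rescaling to a common sum also moved the higher share from 48.0% to 60.0% between the 6 h libraries and from 30% to 41.5% for the difference of the 6 h response. It brought the 48 h responses near an even split, from 59.1% to 51.2% in WT and from 60.5% to 51.5% under the label Zak-deficient. Rescaling to a common sum moved the median of all genes by -0.12 in the 48 h response under the label Zak-deficient, and upper quartile scaling by -0.10 in that of WT; the other shifts were smaller.

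Of 139 list medians outside the random range, 139 kept their direction and call with median ratio scaling, 137 with rescaling to a common sum or to the upper quartile, 119 with centring on GC content and length and 118 with all members above 0. Of the 133 that could be computed without genes with a shared sequence, 97 did. A median moved to the other side of its random lists in 12 cases, for which the cause was not tested. With a mean of 5 FPKM or more these were Th1 genes at 6 h under the label Zak-deficient (-0.41), chemokine receptors at 6 h in WT (-0.34), interferon-stimulated genes at 48 h in WT (0.15) and under the label Zak-deficient (0.19), and the difference of the 48 h cytokine response (0.11). The last was 0.10 with a pseudocount of 0.1 FPKM. With all members above 0, and with no filter, chemokine receptors at 6 h in WT had -0.10 and histone genes between the 6 h libraries 0; cytokine genes between the 0 h libraries had 0 with all members above 0. Without genes with a shared sequence, the TGF-beta difference at 6 h was 0.00107. Without those genes the MHC class I median at 48 h changed sign but kept its side (0.09 in WT and 0.08 under the label Zak-deficient). Medians of 0 that kept their side were found for cytokine genes with no filter at 0 h, and at 48 h and in the 48 h difference both with no filter and with all members above 0.

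Between the labels, several lists kept their call in every setting run. At 0 h these were the TCR-induced and regulatory T cell lists and NF-kB targets. At 6 h they were the TCR-induced, interferon-stimulated, inhibitory receptor and memory and effector lists. At 48 h they were the naive, ribosomal protein, ribosome biogenesis, translation factor, unfolded protein response and G2 and M phase lists. Among 112 values of named genes, 58 moved with a pseudocount of 5 FPKM, 36 with one of 0.1 FPKM and 15 with rescaling to a common sum. The number called reversed was 0, but only values at least 2-fold apart could be called so. A pseudocount cannot turn the sign of a ratio of 2 libraries, so that number is no check of direction. The labels pair no animals across groups. A model with label and time as additive terms would leave 2 residual degrees of freedom, but it takes the label difference to be equal at all 3 times, and it was not fitted. Depth limits low genes: 1 fragment of a 939-base transcript was estimated at about 0.07 FPKM.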

Other observations

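The test on genes apart by a smaller margin was chosen before its result was seen, and those on the genes apart at all 3 times and on the summed copies of Eif3j after. Among the helper lineage genes given here, Bcl6 and Foxp3 changed with time in both labels. Bcl6, the factor of follicular helper cells, stood at 31.6 FPKM in WT and 40.2 under the label Zak-deficient at 6 h, against 7.67 and 6.98 at rest. Foxp3 stood at 40.3 and 44.7 at 6 h and 5.90 and 7.65 at 48 h. Gata3 lay between 6.26 and 9.85 in the 6 libraries, and Tbx21 stayed at 0.52 or lower.

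Sums of markers of other cell types rested mostly on a few genes. Myeloid markers summed to between 92.4 and 141.6 FPKM, but Ctss alone gave 127.6 of the 141.6, while Lyz2 was at most 0.36 and Csf1r at most 0.26. CD8 T cell markers summed to 55.8 and 51.1 at rest in the 2 labels and to 16.6 and 20.4 at 48 h, with Klrd1 at 40.4 and 37.3 at rest, Cd8b1 between 8.11 and 12.04 and Cd8a at most 1.02 in any library. These single genes were chosen after their values were seen. Natural killer and innate lymphoid markers summed to 9.03 and 10.97 at rest and 1.72 and 2.77 at 48 h, and gamma-delta T cell markers to 0.40 or less in each library. Erythroid markers summed to 0.16 in the 48 h library labelled Zak-deficient and to between 1.31 and 2.60 in the others. None of the erythroid markers reached a mean of 1 FPKM. Summed Y-linked genes lay between 1.72 and 3.11 FPKM in all 6 libraries, while Xist was not in the table, so sex was not compared further.

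Some genes were apart in the same direction between the labels at all 3 times, by 0.4 or more on the log2 scale, and were chosen after their values were seen. They were 12 in number. Sord stood at 3.34 FPKM under the label Zak-deficient against 1.57 in WT at 0 h, 1.69 against 0.94 at 6 h and 17.15 against 6.5 at 48 h, Cdk5rap1 at 13.09 against 6.39, 11.35 against 6.35 and 11.06 against 5.75, and Ube2e3 at 11.72 against 18.30, 11.84 against 21.13 and 14.70 against 20.14. Of the 12, 58.3% lie on chromosome 2, against 8.33% in the median random set, and so does Map3k20. Their starts run from 78868236 (Ube2e3) to 177903064 (Zfp972), the last over 100 Mb from Map3k20. Of 45 genes apart by a smaller margin, 24.4% lie there, above the 17.8% that bounds the central 95% of random sets, and the 11 start between 30.3 and 140.1 Mb, a wide span. A stretch of chromosome 2 from another strain, kept beside the altered Map3k20 gene, is a candidate explanation, as is an effect of Zak deficiency on these genes, which was not tested.

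Eif3j1 was lower and Eif3j2 higher under the label Zak-deficient at all 3 times. The log2 ratio of their summed FPKM was at most 0.211 from 0 (-0.211 at 6 h), so reads assigned to one copy in place of the other may account for most of both differences. A strain variant in either copy would have this effect, and was not tested on reads.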
